A study of Mus musculus with 6 samples.

How the data were processed

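Livers of wild-type mice and of mice lacking Cugbp1, the RNA-binding protein gene now named Celf1, were collected at day 3 of life, and their total RNA was labelled with the dye Cy3 and hybridised to whole-mouse-genome oligonucleotide arrays, per the labels. There were 3 arrays of each genotype and no other samples. Nothing in the labels says whether replicates came from separate litters, and p-values measure the spread between these 6 samples.

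Agilent Feature Extraction is named in the submitters' processing notes, with no version given. The authors deposited 1 table of linear signal intensity, with 55681 probes and 1 value per probe and array. It held no control probes, detection flags or background columns, 91 empty cells spread over 90 probes, and 17186 probes without a gene name. Which scanner column the intensity was taken from is not given in the sources used here. The authors also deposited a value table on the log2 scale. It was recomputed from the intensities by quantile normalization, log2 and subtraction of each probe's median over the 6 arrays, and on the array with the lowest share, knockout 3, 99.96% of probes were equal within 0.01. Scale, centring and direction of the deposited log2 values are therefore settled. The medians of its columns were 0.005, 0.001 and 0.004 for wild-type 1, 2 and 3 and 0.001, -0.011 and -0.011 for knockout 1, 2 and 3.

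Gene names came from the signal table and were brought up to date through a gene table of the GRCm38.p6 assembly. Of the probes, 27364 carried a current symbol, 3652 an older symbol that was updated, 2993 a name kept as given, and 4486 an accession or gene model kept as given. That gene table was also used for which genes neighbour Celf1; no reference genome was used here, so positions of the probes along their transcripts are unknown.

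Intensities were divided by each array's 75th percentile, brought back to the common level, given a floor of 1 and transformed to log2. Because no flags were at hand, a probe was taken as detected above the 30th percentile of its array, and it was tested if detected on all 3 arrays of at least 1 genotype. Each gene was represented by its probe with the highest mean, and probes without a name were kept by themselves, which left 30929 features, 21627 of them named. Where a probe lay at or under the detection level on all arrays of a genotype, the fold is given as a lower bound, with the dim arrays set at the detection level.

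Knockout was compared with wild-type in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all features and a threshold of adjusted p 0.05. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1. There were 39 gene lists, each written from textbook knowledge of liver functions, responses and cell types, markers of neighbouring tissues included. Of these, 38 had at least 5 tested genes and were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 38 lists; an estimated correlation and fry were alternatives. The sex-linked list had 0 tested genes and is given as values.

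The groups, tests, lists, most alternatives and the rule for naming genes were set before the data were examined. Celf1 is named first. The genes with the largest differences among those past the threshold follow, or, where fewer than 5 pass in a direction, as here, the 8 genes with a symbol and the smallest unadjusted p in that direction. Also named are up to 4 members with the smallest unadjusted p from each list past its threshold and the members of the CELF and sex-linked lists. Some genes that this rule gives are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

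The labels number the arrays of each genotype 1 to 3. After removal of group means, arrays with the same number correlated across features at 0.36, 0.26 and 0.30, and every other pairing of a wild-type with a knockout array was negative. Removal of group means itself pushes the other pairings below 0 once same-numbered arrays correlate, so their negative sign is no separate support. From the same-number values, and not from the labels, the numbers were taken to pair the arrays. A fit with the replicate number as a block was run as an alternative. By sex-linked transcripts replicate 1 was the only male pair, so for it the check does not separate sex from a shared litter or batch.

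The fit was tested on simulated data with 30892 genes, 200 of them changed. It recovered 1.6%, 40%, 72.4% and 89.6% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 4.6 false calls per run over 5 runs. Simulated genes were independent of each other, so this says nothing on the correlation within gene lists. Their noise was normal, with variances drawn from the fitted prior, and the number of changed genes was set. The recovered shares hold for that setting and do not give the power in the real data. The number of arrays limits the precision of every value below. Alternatives covered the scaling, the deposited log2 values, the filter, the variance prior, array weights, the replicate block, the summary of probes, each array left out in turn, the threshold and the set test. After the data were seen, a sex covariate, a skeletal muscle covariate, a detection level at the 50th percentile, and fits on 4 and on 3 arrays were added.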

Results

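The livers of 3 wild-type and 3 Cugbp1 knockout newborn mice were compared on one-colour arrays at day 3 of life, to ask which hepatic transcripts differ when the CUG-binding protein CELF1 is lost. CELF1 binds GU-rich elements in transcripts and acts on their splicing, decay and translation. The 75th percentile of the raw signal lay between 350.2 on knockout 1 and 534.8 on knockout 2, and the median signal between 34.5 and 48.9 on the same arrays. Arrays correlated at 0.955 to 0.984 across features.

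Celf1, the targeted gene, was lower on all 3 knockout arrays than on all 3 wild-type arrays. Its log2 signal was 11.89 ± 0.14 in wild-type and 8.86 ± 0.22 in knockout (SD, n = 3 each), a difference of -3.03 ± 0.22 (SE) or 8.15-fold, with adjusted p = 0.0556 by limma. A second probe differed by -3.55, from 10.50 ± 0.83 to 6.96 ± 0.73. Each probe gave p = 0.1 in an exact two-sided permutation test, the smallest that 3 arrays against 3 allow. The difference stayed between -3.29 and -2.90 over 23 alternatives, while limma's adjusted p ran from 0.00853 to 0.473 and passed 0.05 in 5 of them. Whether either probe lies in the deleted part of the gene is unknown, so the level is a check of the labels only as far as the probes respond to the deletion.

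**Figure D1:**
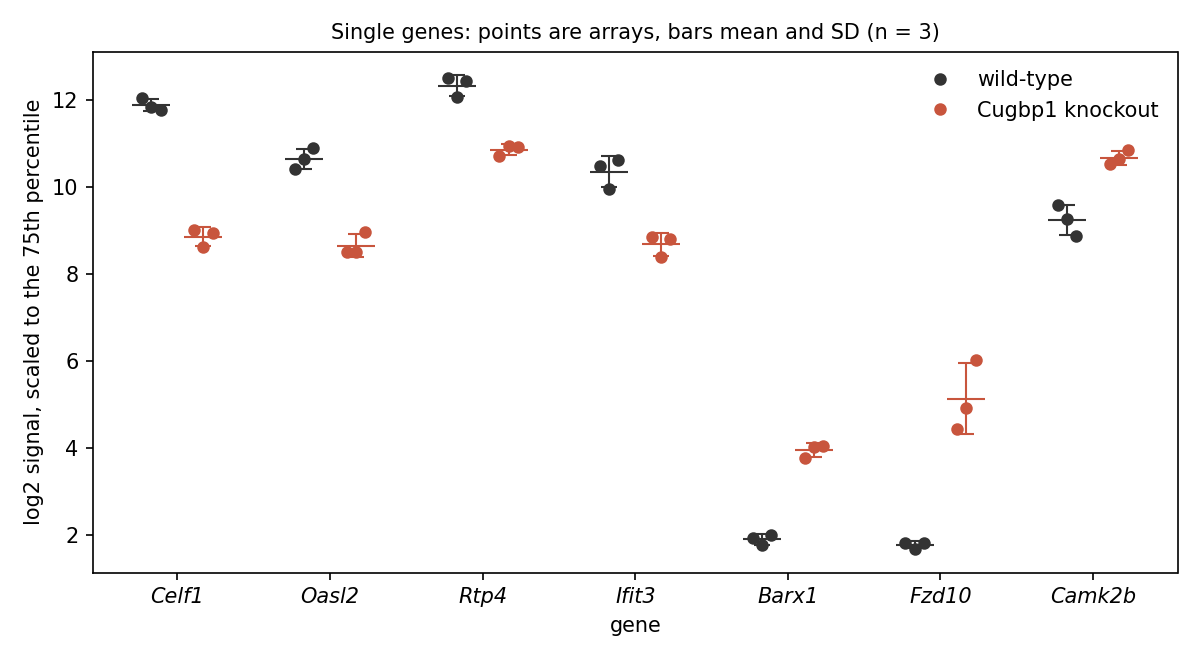
Log2 signal scaled to the 75th percentile (y axis) of 7 genes (x axis), with 1 point per array, wild-type in black and knockout in red, and bars for the mean and SD of 3 arrays. None of these genes passed adjusted p 0.05, and Celf1 lay at 11.89 in wild-type and 8.86 in knockout.

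Across the 30929 features tested, 1 passed adjusted p 0.05 by limma, 0 of them higher and 1 lower in knockout. With the replicate number as a block 0 features passed. The count was 0 without wild-type 1, wild-type 2, wild-type 3 or knockout 1, and 1 without knockout 2 or knockout 3. An unadjusted p under 0.05 was found for 923 features, 478 higher and 445 lower, where chance alone gives 1546. That count was 1577 with the replicate number as a block and 3295 with array weights. The groups did not overlap in 6.74% of features, where chance gives 10%.

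No gene named here passed over all genes, so those that follow are given as values. The smallest unadjusted p among higher genes belonged to Barx1, a homeobox gene, at 2.05 ± 0.21 (log2 difference ± SE, adjusted p = 0.158 by limma), Insyn1 at 1.73 ± 0.20 and Fzd10, a Wnt receptor gene, at 3.36 ± 0.41. Barx1, Insyn1, Fzd10, Lipn and Slco5a1 lay under the detection level on all 3 wild-type arrays. They were at least 2.30-fold, 1.84-fold, 5.22-fold, 1.47-fold and 2.88-fold higher, and Lipn differed by 1.47 ± 0.20. These genes entered the test through the knockout arrays alone. Their SE, p and place in the ranking rest in part on wild-type values near the floor. Mid1, an X-linked ubiquitin ligase gene, differed by 3.05 ± 0.40, a further Mid1 probe by 2.99 and another by -0.66. Ldlrad4 differed by 1.45 ± 0.24 and Camk2b, a calcium/calmodulin-dependent kinase gene, by 1.43 ± 0.26. Slco5a1 differed by 1.81 ± 0.31, with a further probe at -0.0098. That further probe represented Slco5a1 in the fit without wild-type 2, which gave -0.31. Among lower genes, Celf1 was followed by Oasl2 (-1.99 ± 0.25, adjusted p = 0.291), Rtp4 (-1.47 ± 0.22) and Ifi27l2a (-2.04 ± 0.32), all known as interferon-induced. Ifit3 (-1.66 ± 0.27), Fhad1 (-1.40 ± 0.24) and Orm2 (-2.09 ± 0.36) came next, and a further Fhad1 probe differed by -0.20.

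None of the other CELF and muscleblind-like genes, which encode RNA-binding proteins, passed over all genes. Celf6 differed by 0.50 ± 0.24 (log2 ± SE), Mbnl3 by 0.52 ± 0.36, Celf2 by 0.16 ± 0.19, Celf5 by 0.14 ± 0.20, Celf3 by 0.12 ± 0.25, Celf4 by 0.0032 ± 0.28, Mbnl1 by -0.14 ± 0.23 (a further probe by -0.81) and Mbnl2 by -0.04 ± 0.29. The sign of Celf4 turned under median scaling (-0.018) and without wild-type 2 (-0.062), knockout 1 (-0.020) or knockout 3 (-0.21), and further Celf4 probes differed by 0.17 and -0.19. That of Mbnl2 turned without scaling (0.074) and without wild-type 1 (0.063), wild-type 3 (0.053), knockout 1 (0.058) or knockout 2 (0.060), and that of Celf3 without knockout 2 (-0.069). Over the list alone 1 of 9 members, Celf1, passed. Its median was 0.12 while its mean was -0.20, and camera gave adjusted p = 0.915 and adjusted p = 0.979 with an estimated correlation. The 18 transcripts described as CELF1 targets or GU-rich-element genes had a median of -0.21, with 12 lower and 6 higher. Camera gave adjusted p = 0.575, with 0 members past over all genes or adjusted over the list alone. That median turned to 0.11 without wild-type 3 and to 0.10 without knockout 2. It stayed negative without any other single array, at -0.41 without wild-type 2.

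Interferon-stimulated genes were lower in knockout liver. All 35 tested members had a negative log2 difference, with a median of -1.17. On 23 of them the 3 knockout arrays lay under all 3 wild-type arrays, and on 0 above. Over all features the groups did not overlap in 6.74%, both directions counted, where chance gives 10%. Oasl2 differed by -1.99, Rtp4 by -1.47, Ifit3 by -1.66 and Ifit1 by -1.88 ± 0.35 (SE), the last from 8.86 ± 0.45 to 6.99 ± 0.48 (SD, n = 3). Adjusted over the list alone 17 of 35 members passed, and over all genes 0 did. Camera gave adjusted p = 1.73e-34 with the preset correlation and adjusted p = 0.251 with an estimated correlation of 0.334. The median lay between -1.31 and -0.89 when any 1 array was left out, and at -1.48, -0.71 and -0.93 within the pairs 1, 2 and 3.

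**Figure D2:**
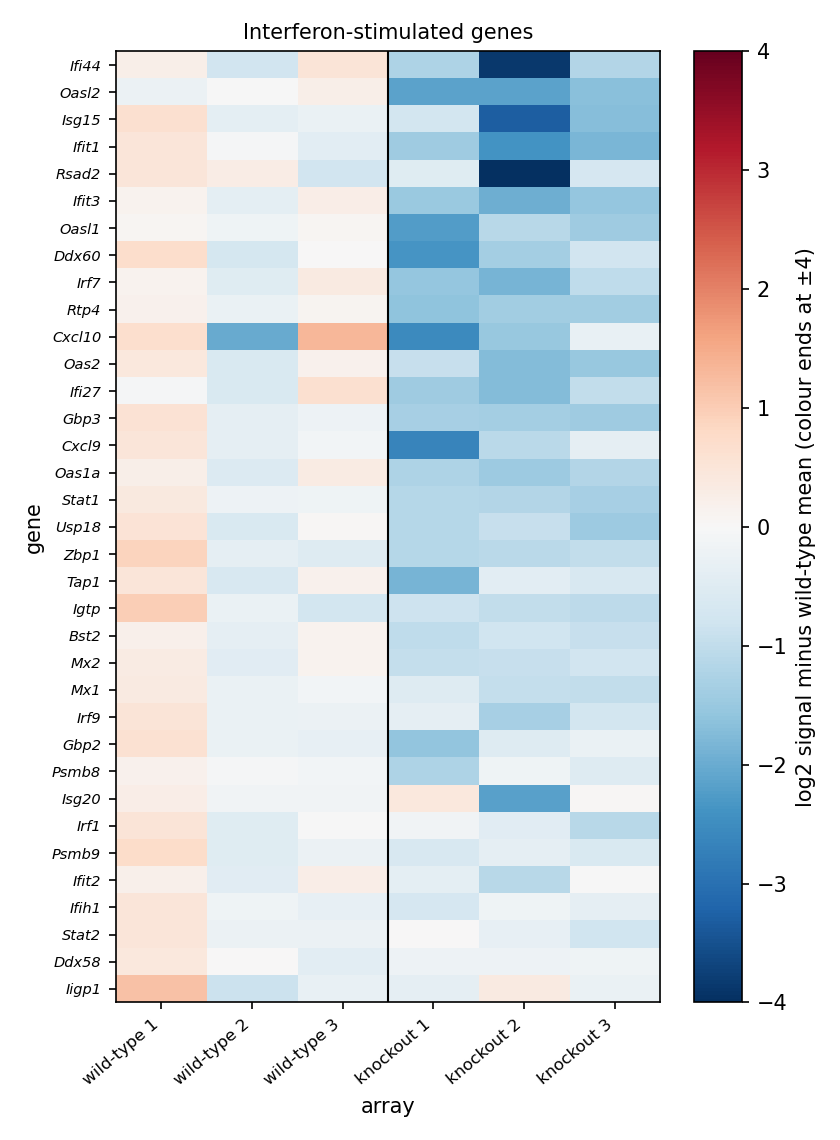
Log2 signal minus the wild-type mean (colour, ending at 4 in either direction) of the 35 interferon-stimulated genes (y axis) on the 6 arrays (x axis), ordered by the knockout mean. The knockout arrays are mostly blue, with a median difference of -1.17 over the list.

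Of the 38 lists, 11 passed adjusted p 0.05 by camera with the preset correlation, 9 lower and 2 higher, and 0 passed with an estimated correlation. Without knockout 2 the count was 20. Every other split of the 6 arrays into 3 and 3 gave more, from 12 to 19 lists, so the number of lists past the threshold does not set the genotypes apart from other groupings.

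Genes of secreted liver proteins were lower by small amounts. Of 24 hepatocyte secreted protein genes 21 were lower, with a median of -0.30 and adjusted p = 7.68e-07, or adjusted p = 0.251 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. Ambp differed by -0.40, Apoc3 by -1.82 (a further probe by -0.84), Apoe by -0.44 and Apoc1 by -0.38. Quantile normalization and the deposited log2 values each brought this median to -0.069 and ended the call. Acute-phase genes had a median of -0.40, with 20 of 26 lower and 6 higher. Camera gave this list adjusted p = 6.04e-06, or adjusted p = 0.251 with an estimated correlation. Among the 6 higher members, Hamp, chosen after its values were seen, differed by 1.80 with no overlap between the groups. Orm2 (-2.09 ± 0.36), Orm1 (-2.39 ± 0.44) and Fgl1 (-1.10 ± 0.25) passed adjusted over the list alone, 3 members in all against 0 over all genes, and Saa2 differed by -2.35 ± 0.80.

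The median pancreas marker was high on 1 array and the median muscle marker on 3. Single pancreas markers also differed on other knockout arrays. Try5 lay at 6.03 and Cpb1 at 5.75 on knockout 3, against 3.00 and 3.93 on their highest wild-type arrays. On 6 of the 16 pancreas markers all 3 knockout arrays lay above all 3 wild-type arrays, and on 0 below. Over all features the groups did not overlap in 6.74%. The median exocrine pancreas marker lay 67.2-fold above the mean of wild-type 1 and 2 on knockout 2, and within 1.27-fold of it on the other arrays. Over both groups the pancreas list was higher in knockout by a median of 2.51, with 14 of 16 members higher and adjusted p = 6.04e-06, or adjusted p = 0.974 with an estimated correlation. Pnliprp1 differed by 2.99 ± 1.29 (SE), Cpb1 by 5.31 ± 2.48, Try5 by 5.64 ± 2.75 and Amy2a5 by 1.74 ± 0.93 (a further probe by 0.74). Skeletal muscle markers lay 52.3-fold, 22.4-fold and 190.5-fold above the same level on wild-type 3, knockout 2 and knockout 3. That list had a median of 2.23, with 14 of 15 members higher and adjusted p = 0.00117, or adjusted p = 0.974 with an estimated correlation. Mylpf differed by 2.09 ± 1.23, Ckm by 3.67 ± 3.06, Tnnt3 by 3.40 ± 2.88 and Tnnt1 by 1.07 ± 0.95. In neither list did a member pass over all genes or adjusted over the list alone. The muscle median fell short of the threshold without wild-type 1 (1.41), wild-type 2 (1.34) or knockout 3 (0.57), and moved to 4.01 without wild-type 3 and 4.45 without knockout 1. The pancreas call by camera with the preset correlation stayed with any 1 array left out. Its median was 0.35 without knockout 2 and 3.81 without knockout 1.

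**Figure D3:**
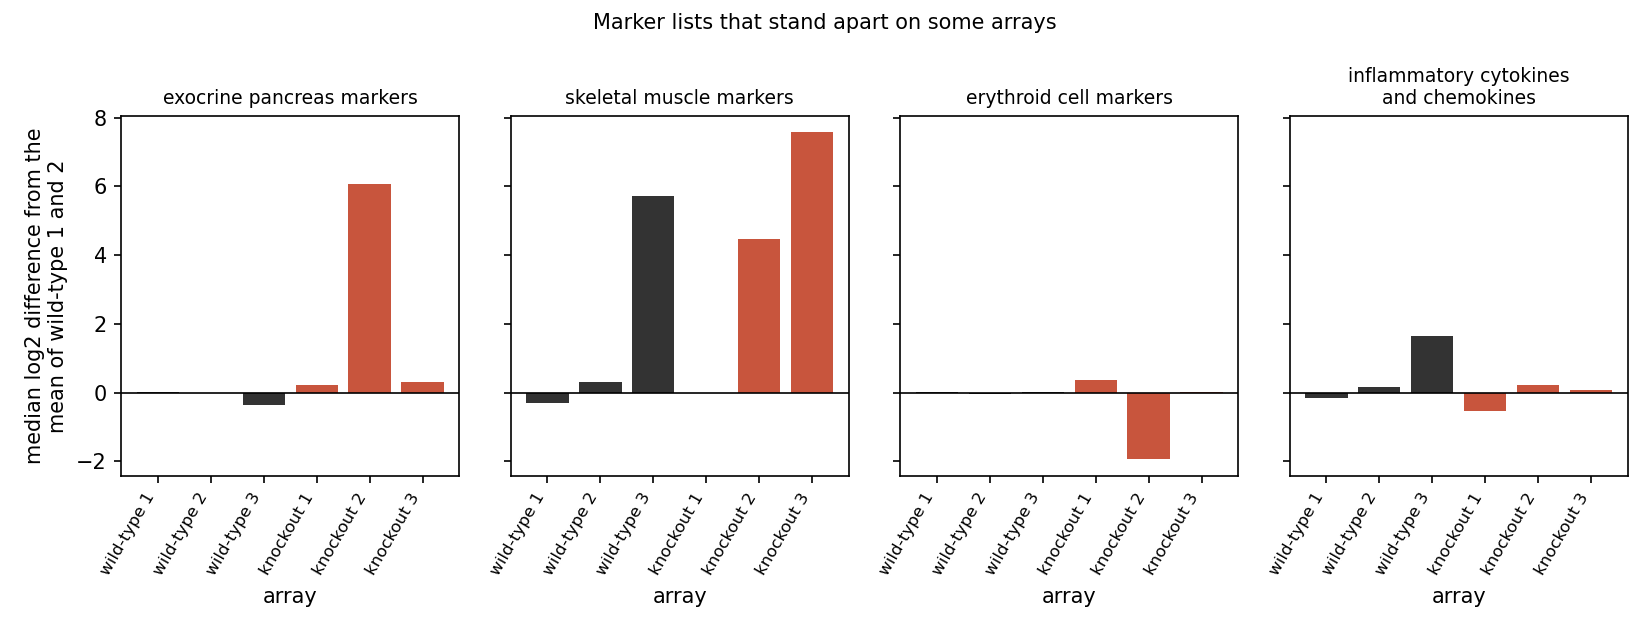
Median log2 difference of 4 lists (y axis) on each of the 6 arrays (x axis) from the mean of wild-type 1 and 2, a reference chosen after the data were seen; wild-type bars are black and knockout bars red. Pancreas markers stand at 6.07 on knockout 2, and muscle markers at 5.71, 4.48 and 7.57 on wild-type 3, knockout 2 and knockout 3.

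Blood cell lists had lower medians in knockout, but the erythroid list through 1 array, and the platelet and granulocyte calls rested on wild-type 3. Erythroid markers had a median of -0.44, with 28 of 31 lower and adjusted p = 0.00269, or adjusted p = 0.974 with an estimated correlation. Knockout 2 was the array with high medians of both pancreas and muscle markers. There the erythroid median lay at -1.94 against wild-type 1 and 2. Without that array the erythroid list turned to 0.27, with adjusted p = 3.38e-04 by camera. It was -0.86 without knockout 1 and -0.71 without knockout 3. Hemgn differed by -0.32, Hbb-y by 1.41, Tfrc by -0.35 (further probes by -0.68 and -0.51) and Car1 by -0.44. All 15 megakaryocyte and platelet markers were lower, with a median of -0.25 and adjusted p = 5.48e-04, or adjusted p = 0.974 with an estimated correlation; Vwf differed by -1.07, Treml1 by -0.43, Itga2b by -0.57 and Pf4 by -0.33. Granulocyte markers had a median of -0.18, with 20 of 22 lower and adjusted p = 0.00269, or adjusted p = 0.974 with an estimated correlation; Ctsg differed by -0.49, Prtn3 by -0.45, Elane by -0.56 and Chil3 by -0.60. No member of the 3 lists passed over all genes or adjusted over the list alone. Against wild-type 1 and 2, granulocyte markers stood at 0.40 on wild-type 3 and at 0.041, -0.24 and 0.0096 on knockout 1, 2 and 3. Platelet markers stood at 0.33 on wild-type 3 and at -0.47, -0.079 and -0.083 on knockout 1, 2 and 3. Without wild-type 3 the platelet and granulocyte calls ended, at -0.15 and -0.073, and without knockout 1 the platelet call ended at -0.21. The granulocyte median was -0.37 without wild-type 2 and -0.27 without knockout 3.

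Chemokine, cell death, glycolysis and immediate early genes were high on wild-type 3, 1 of the arrays with muscle transcripts. Against wild-type 1 and 2, the medians on that array were 1.66 for inflammatory cytokines and chemokines, 0.81 for p53 targets, 1.03 for glycolysis and 2.13 for immediate early genes, which stood at 1.11 on knockout 3. The cytokine list had a median of -0.28 in knockout, with 15 of 23 lower and adjusted p = 0.0192, or adjusted p = 0.974 with an estimated correlation; Ccl12 differed by -1.30, Ccl7 by -3.13, Ccl2 by -2.79 and Ccl4 by -1.49. The list of p53 targets and cell death genes had a median of -0.42, with 17 of 19 lower and adjusted p = 0.0015, or adjusted p = 0.974 with an estimated correlation; Phlda3 differed by -0.87, Bax by -0.42, Gadd45b by -1.10 and Gadd45a by -0.84. Glycolysis had a median of -0.30, with 17 of 19 lower and adjusted p = 0.0194, or adjusted p = 0.974 with an estimated correlation; Pfkp differed by -1.53 (a further probe by -0.33), Eno1 by -0.45 and Gpi1 by -0.78. No member of these lists passed over all genes or adjusted over the list alone. Without wild-type 3 all 3 calls ended, with medians of -0.00055, -0.074 and -0.072; they also ended without knockout 1, at -0.11, -0.43 and -0.34, and the glycolysis call ended without knockout 2, at -0.17. Without wild-type 1, wild-type 2 and knockout 3 the p53 median was -0.68, -0.75 and -0.67; the cytokine median was -0.84 without wild-type 1 and -0.58 without knockout 3, and the glycolysis median -0.59 without wild-type 2.

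The other lists of liver function did not pass over all 6 arrays, though several did, in camera with the preset correlation, when a single array was left out. Hepatocyte genes that rise after birth had a median of 0.33 (adjusted p = 0.206 by camera) and fetal liver genes that fall after birth 0.067 (0.688). Among metabolic lists the medians were 0.20 for cholesterol synthesis and uptake (0.22), -0.047 for the urea cycle and amino acid catabolism (0.318), -0.05 for fatty acid synthesis and storage (0.406) and 0.054 for fatty acid oxidation (0.982). They were 0.078 for bile acid synthesis (0.915), -0.21 for xenobiotic metabolism (0.647), 0.049 for oxidative phosphorylation (0.483) and -0.18 for gluconeogenesis and glycogen metabolism (0.538), where 1 member passed adjusted over the list alone. The growth hormone axis stood at 0.074 (0.688), circadian clock genes at -0.08 (0.915), complement and coagulation at 0.047 (0.559) and cytosolic ribosomal proteins at -0.079 (0.0551). Without knockout 2, calls were made for the urea cycle (-0.38, adjusted p = 5.82e-06), xenobiotic metabolism (-0.62, 1.22e-04), fatty acid oxidation (-0.26, 0.00126), bile acids (-0.17, 0.0240), complement (-0.19, 0.0287), cholesterol synthesis (0.39, 0.0467), ribosomal proteins (-0.14, 0.0057) and oxidative phosphorylation (-0.11, 0.0246). The last was called at 0.19 (0.0139) without knockout 1, as were genes that rise after birth at 0.58 (0.0211). Without wild-type 1 the calls were cholesterol synthesis at 0.65 (1.32e-07), genes that rise after birth at 0.65 (0.00695) and ribosomal proteins at -0.17 (0.00596). Without wild-type 3 they were bile acids at -0.37 (0.0106) and complement at -0.12 (0.0204), and without knockout 3 fatty acid synthesis at -0.19 (0.0307).

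Stress, growth and cell type lists did not pass over all 6 arrays either. Medians were 0.083 for the unfolded protein response (adjusted p = 0.22 by camera), -0.039 for heat shock proteins (0.406), 0.0027 for oxidative stress and metallothioneins (0.688), -0.22 for immediate early genes (0.538) and -0.0059 for the cell cycle (0.915). Among cell types they were -0.12 for macrophages and Kupffer cells (0.559), -0.094 for lymphocytes (0.22), -0.074 for liver endothelium (0.462), -0.094 for stellate cells and fibroblasts (0.397) and -0.073 for cholangiocytes and progenitors (0.915). Gut epithelium markers stood at 0.12 (0.322). Some of these lists were called in opposite directions when different single arrays were left out. The cell cycle was called at 0.36 (adjusted p = 2.25e-10) without knockout 2, and at -0.27 (0.0308) and -0.20 (0.0215) without knockout 1 and knockout 3. Immediate early genes were called at 0.44 (2.49e-04) without wild-type 3, and at -0.61 (0.0173) and -0.59 (0.00172) without wild-type 2 and knockout 3. Stellate cells were called at 0.21 (0.0199) without wild-type 3, and at -0.40 (0.00185) and -0.29 (0.00878) without wild-type 1 and knockout 3. Macrophages were called at 0.14 (0.0459) without knockout 1, and at -0.24 (0.0412) and -0.30 (0.00108) without wild-type 1 and knockout 2. Further calls were endothelium at -0.28 (0.00185) without wild-type 1, lymphocytes at -0.22 (0.0460) without knockout 3 and the unfolded protein response at 0.26 (0.0116) without wild-type 3. Among the lists that did not pass, camera's direction was opposite to the median for complement and coagulation, bile acid, circadian clock, CELF and oxidative stress genes, and the mean opposite to the median for CELF, oxidative stress, cholangiocyte and fatty acid oxidation genes. The median of 26 of these 27 lists changed sign under at least 1 alternative.

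Sex-linked transcripts divided both genotypes alike. Ddx3y and Eif2s3y, on the Y chromosome, had log2 signals of 10.66 and 11.74 on wild-type 1 and of 10.67 and 11.61 on knockout 1, and lay under the detection level on the other 4 arrays. Kdm5d and Uty were likewise detected on wild-type 1 and knockout 1. Xist, the transcript of the inactive X chromosome, by its brighter probe lay between 10.05 and 10.82 on those 4 arrays and at 1.75 and 2.10 on wild-type 1 and knockout 1. The labels describe the knockout mice as male, which these values match on 1 of 3 knockout arrays. With sex as a covariate 0 features passed adjusted p 0.05 by limma, where 1096 had an unadjusted p under 0.05.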

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

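The sex and muscle covariates, the 50th percentile as a detection level and the fits on 4 and on 3 arrays were tests chosen after the data were seen. Only 6 arrays bear on every result, and signal near the array floor limits Barx1, Insyn1, Fzd10, Lipn and Slco5a1 to a bound in wild-type. Of the 11 lists past adjusted p 0.05, 2, interferon-stimulated and acute-phase genes, kept their call in every alternative with the preset correlation, and 18 of the 27 lists without a call gained one in at least 1. With the estimated correlation or the one-way fry test 0 lists passed. With the mixed fry test 3 did, interferon-stimulated and hepatocyte secreted genes and the CELF list (0.12). The CELF list holds Celf1, its only member past adjusted over the list alone. Its call cannot be told apart from the deletion, since the list was not tested without Celf1. Fry asks whether a list's genes move, on balance, one way or in either direction, not whether they differ from other genes. Medians do not change with the set test and stayed at -1.17 for interferon-stimulated genes, -0.40 for acute-phase, -0.44 for erythroid, 2.51 for pancreas, -0.30 for glycolysis, -0.18 for granulocyte, -0.30 for hepatocyte secreted, -0.28 for cytokine, -0.25 for platelet, -0.42 for p53 and 2.23 for muscle genes. Of the 63 genes other than Celf1 that the naming rule gives, 8 changed sign under at least 1 alternative and 4 passed adjusted p 0.05 under at least 1. Slco5a1, among the 8, did so through a change of the probe that represented it. Without scaling, the median of all features moved to 0.11. The count of genes was 1 as reported and became 0 with no filter, detection on all 6 arrays, the replicate block, the sex covariate, the muscle covariate, and on 4 or 3 arrays, with 0 lower. It was 2 (2 lower) with median scaling, an intensity trend or a detection level at the 50th percentile, 3 (1 higher, 2 lower) with probes tested by themselves, 4 (1 higher, 3 lower) at adjusted p 0.10 and 11 (7 higher, 4 lower) with array weights. With any 1 array left out it was 0 to 1, with 0 to 1 higher and 0 to 1 lower. The count of lists was 11 to 20 with any 1 array left out, 20 without knockout 2, and 17 on 3 arrays. With fewer arrays, fewer residual degrees of freedom remain; for every other change the cause was not tested. The replicate block changed no call besides that count. In the fit on 3 arrays the lone knockout array is assumed to vary like the wild-type arrays. Not run were normexp background correction, since the columns it needs were not at hand, and a slide or scan block, since neither was given.

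Values in parentheses are log2 differences, medians for lists. Median scaling brought a call to Celf1 (-3.05) and ribosomal proteins (-0.10). Median scaling turned the sign of Celf4 (-0.018) and oxidative stress (-0.018). An intensity trend in the prior brought a call to Celf1 (-3.03) and ribosomal proteins (-0.079). Array weights ended the call of erythroid cell (-0.038), granulocyte (-0.070), platelets (-0.13) and p53 targets and cell death (-0.12). Array weights brought a call to Celf1 (-3.00), ribosomal proteins (-0.14), the urea cycle (-0.39), Barx1 (2.14), Fzd10 (4.0) and Insyn1 (1.72). Array weights turned the sign of Celf3 (-0.092), Mbnl2 (0.27), bile acids (-0.29), cell cycle (0.21), circadian clock genes (0.010), complement and coagulation (-0.16), fatty acid oxidation (-0.32), gluconeogenesis (0.041) and glycolysis (0.015). Array weights turned the sign of immediate early genes (0.59), cytokines (0.0065), the growth hormone axis (-0.0039), endothelium (0.053), macrophages (0.13), oxidative stress (-0.033), stellate cells (0.40) and CELF1 targets (0.13). Probes tested by themselves brought a call to Celf1 (-3.03), ribosomal proteins (-0.083) and genes that rise after birth (0.39). Probes tested by themselves turned the sign of cholangiocytes (0.0039) and complement and coagulation (-0.038). A detection level at the 50th percentile brought a call to Celf1 (-3.03). A detection level at the 50th percentile turned the sign of cholangiocytes (0.0039), circadian clock genes (0.035) and complement and coagulation (-0.0032). 3 arrays (wild-type 1 and 2, knockout 1) ended the call of exocrine pancreas (0.15) and p53 targets and cell death (-0.23). 3 arrays (wild-type 1 and 2, knockout 1) brought a call to fatty acid synthesis and storage (-0.39), lymphocyte (-0.25), macrophages (-0.59), the urea cycle (-0.66) and xenobiotic metabolism (-0.58). 3 arrays (wild-type 1 and 2, knockout 1) turned the sign of Celf3 (-0.15), Elane (0.092), Gadd45a (0.043), Mbnl1 (0.23), Tfrc (0.12), bile acids (-0.66), cell cycle (0.48), complement and coagulation (-0.17) and ribosomal proteins (0.036). 3 arrays (wild-type 1 and 2, knockout 1) turned the sign of erythroid cell (0.38), fatty acid oxidation (-0.49), glycolysis (0.017), granulocyte (0.041), genes that rise after birth (-0.41), immediate early genes (0.24), oxidative phosphorylation (-0.12), oxidative stress (-0.057) and skeletal muscle (-0.12). 3 arrays (wild-type 1 and 2, knockout 1) turned the sign of CELF1 targets (0.088). 4 arrays (without wild-type 3 and knockout 2) ended the call of exocrine pancreas (0.21) and cytokines (-0.096). 4 arrays (without wild-type 3 and knockout 2) brought a call to fatty acid synthesis and storage (-0.18), the urea cycle (-0.58) and xenobiotic metabolism (-0.60). 4 arrays (without wild-type 3 and knockout 2) turned the sign of Celf3 (-0.17), Mbnl2 (0.15), bile acids (-0.53), cell cycle (0.43), circadian clock genes (0.081), complement and coagulation (-0.25), erythroid cell (0.22), fatty acid oxidation (-0.61) and gluconeogenesis (0.036). 4 arrays (without wild-type 3 and knockout 2) turned the sign of glycolysis (0.13), granulocyte (0.024), gut epithelium (-0.021), genes that rise after birth (-0.16), immediate early genes (0.77), endothelium (0.0047), oxidative phosphorylation (-0.061), oxidative stress (-0.11) and p53 targets and cell death (0.026). 4 arrays (without wild-type 3 and knockout 2) turned the sign of stellate cells (0.25) and CELF1 targets (0.20). The mean of a gene's probes brought a call to ribosomal proteins (-0.10). The mean of a gene's probes turned the sign of Celf4 (-0.0046). The muscle covariate brought a call to ribosomal proteins (-0.11), immediate early genes (-0.69), endothelium (-0.25), macrophages (-0.27) and stellate cells (-0.45). The muscle covariate turned the sign of Celf4 (-0.044), cell cycle (0.041), fatty acid synthesis and storage (0.0075) and the growth hormone axis (-0.054). It also turned oxidative phosphorylation (-0.029), oxidative stress (-0.0068) and skeletal muscle (-0.032). That covariate was the mean of the skeletal muscle list on each array, so the loss of that list's own difference was fixed in advance. No scaling turned the sign of Mbnl2 (0.074), cell cycle (0.11), cholangiocytes (0.041), circadian clock genes (0.034), ribosomal proteins (0.035), fatty acid synthesis and storage (0.064), heat shock proteins (0.076), endothelium (0.040) and lymphocyte (0.021). No scaling turned the sign of stellate cells (0.020) and the urea cycle (0.067). No filter ended the call of erythroid cell (-0.44), glycolysis (-0.30), granulocyte (-0.18), cytokines (-0.21), platelets (-0.25) and p53 targets and cell death (-0.39). No filter brought a call to cholesterol synthesis and uptake (0.20), genes that rise after birth (0.33) and the unfolded protein response (0.083). No filter turned the sign of oxidative stress (-0.048). Detection required on all 6 arrays brought a call to ribosomal proteins (-0.079). Detection required on all 6 arrays turned the sign of complement and coagulation (-0.0032). Quantile normalization ended the call of glycolysis (-0.25), granulocyte (-0.13) and hepatocyte secreted proteins (-0.069). Quantile normalization brought a call to oxidative phosphorylation (0.13). Quantile normalization turned the sign of cell cycle (0.0069) and ribosomal proteins (0.049). The deposited value table ended the call of glycolysis (-0.25), granulocyte (-0.13) and hepatocyte secreted proteins (-0.069). The deposited value table brought a call to oxidative phosphorylation (0.13). The deposited value table turned the sign of cell cycle (0.0063) and ribosomal proteins (0.050). Of the lists whose sign turned, cell cycle, complement and coagulation, fatty acid oxidation, immediate early genes and stellate cells also passed adjusted p 0.05 with array weights. Of the lists whose sign turned, bile acids, cell cycle, complement and coagulation, erythroid cell, fatty acid oxidation, genes that rise after birth and oxidative phosphorylation also passed adjusted p 0.05 with 3 arrays (wild-type 1 and 2, knockout 1). Of the lists whose sign turned, bile acids, cell cycle, complement and coagulation, erythroid cell, fatty acid oxidation, genes that rise after birth and immediate early genes also passed adjusted p 0.05 with 4 arrays (without wild-type 3 and knockout 2). For Slco5a1, the fit without wild-type 2 switched to its further probe, which gave the low end of its range below. With any 1 array left out, values ran for Celf3 from -0.069 to 0.23, Celf4 from -0.21 to 0.24, Mbnl2 from -0.24 to 0.063, Slco5a1 from -0.31 to 1.94 and bile acids from -0.37 to 0.32. Likewise they ran for cell cycle from -0.27 to 0.36, cholangiocytes from -0.11 to 0.13, cholesterol synthesis and uptake from -0.33 to 0.65, circadian clock genes from -0.18 to 0.19 and complement and coagulation from -0.19 to 0.17. The range was, for ribosomal proteins from -0.17 to -0.0050, erythroid cell from -0.86 to 0.27, fatty acid oxidation from -0.26 to 0.38, fatty acid synthesis and storage from -0.28 to 0.16 and fetal genes from -0.044 to 0.24. Across the same 6 fits values ran for gluconeogenesis from -0.27 to 0.0020, glycolysis from -0.59 to -0.072, granulocyte from -0.37 to -0.073, gut epithelium from -0.014 to 0.46 and genes that rise after birth from 0.14 to 0.65. Ranges were, for immediate early genes from -0.61 to 0.44, cytokines from -0.84 to -0.00055, the growth hormone axis from -0.055 to 0.072, endothelium from -0.28 to 0.13 and lymphocyte from -0.22 to -0.0065. Further ranges were, for macrophages from -0.30 to 0.14, platelets from -0.36 to -0.15, oxidative phosphorylation from -0.11 to 0.19, oxidative stress from -0.14 to 0.026 and p53 targets and cell death from -0.75 to -0.074. Others were, for skeletal muscle from 0.57 to 4.45, stellate cells from -0.40 to 0.21, CELF1 targets from -0.41 to 0.11, the unfolded protein response from -0.011 to 0.26 and the urea cycle from -0.38 to 0.18. The last were, for xenobiotic metabolism from -0.62 to 0.0083.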

Other observations

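The tests on skeletal muscle tissue and on macrophage and lymphocyte markers, and the genes in the next paragraph, were chosen after the values were seen; the other tests were set before theirs were.

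Serpina6, the gene of corticosteroid-binding globulin, had a log2 signal of 7.82 ± 1.69 in wild-type and 12.55 ± 1.03 in knockout (SD, n = 3), with no overlap and adjusted p = 0.972 by limma. Hamp, the gene of the iron hormone hepcidin, differed by 1.80 with no overlap and adjusted p = 1. The embryonic globin genes Hbb-y and Hbb-bh1 had log2 signals of 11.04 and 9.30 on knockout 1 and of 11.77 and 9.99 on knockout 3, against 8.47 to 8.89 and 7.05 to 8.20 in wild-type. On knockout 2 they lay at 7.68 and 5.70, where Slc4a1, Alas2 and Tspo2, all of red cell precursors, were also low, by -3.50, -2.63 and -3.59 against the other knockout arrays. Wild-type 3 stood above the other wild-type arrays 18.3-fold in Ccl2, 18.3-fold in Il1b and 18.6-fold in Gdf15.

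The lower level of interferon-stimulated genes in knockout was set against 4 technical or cellular explanations. The values argue against a single array and the scaling as the whole cause. The median of -1.17 moved no higher than -0.89 when 1 array was left out and no higher than -1.05 under another scaling. Sex was balanced, with replicate 1 male and replicates 2 and 3 female in both genotypes, so it could not by itself make this difference. The values by sex show only that the list was lower in both, the higher of the medians in the male pair and in the female arrays being -0.77. The lowest 95% bootstrap limit over genes for the macrophage and lymphocyte medians was -0.33, above the limits of -1.39 to -0.81 for the interferon list. These limits resample genes on the same 6 arrays and hold no spread between animals. With any 1 array left out the macrophage median ran from -0.30 to 0.14 and the lymphocyte median from -0.22 to -0.0065. Whether fewer such cells play a part stays open. The 10 splits of 6 arrays into 3 and 3 cannot give a share under 0.05; 1 split, the real one at 1.17, reached that shift, and the highest other was 0.71, or 0.58 among those that part all 3 pairs as the real one does. Genotype, litter and exposure of the animals stay open as well. An effect of the genotype is a hypothesis that may be checked on further litters. With an estimated correlation camera gave the list adjusted p = 0.251.

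Pancreas and muscle markers may come from tissue taken along with some livers, which stays open. Within groups, the 8 brightest pancreas markers had a median pairwise correlation of 0.956 and the 8 brightest muscle markers of 0.978, but the arrays that stand apart set these values and the choice of the brightest markers, so they decide nothing. On knockout 2 Ctrb1 reached 15.16 and Amy2a5 16.40, and on knockout 3 Tnnc2 reached 16.83 and Acta1 16.00. Of 16 pancreas and 15 muscle markers, 14 and 11 were also detected on both wild-type 1 and wild-type 2, and 0 and 1 stand in another list. Detection above the 30th percentile was common. Of features tested, 28586 remained when it was required on all 6 arrays, against 30929 as reported. The counts of detected markers therefore do not show that these livers express them in particular. Only 6 arrays bear on this, and no biological explanation was tested.

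The counts of calls were set against other groupings of the arrays and a carried-over chromosome segment. The 10 splits cannot give a share under 0.05: 4 gave at least the real count of 1 gene, the highest other being 56, and 10 gave at least the real 11 lists, the highest other being 19. The split with 56 genes set wild-type 3, knockout 2 and knockout 3, the arrays with muscle transcripts, against the rest, which points to a structure of the samples other than genotype. Among the 3 other splits that part all 3 pairs, as the real one does, 0 genes and 12 to 17 lists passed; the remaining splits part 1 pair. Of 46 tested neighbours of Celf1, 0 had an unadjusted p under 0.05 against 2.76% of other named genes (one-sided Fisher exact p = 1), but with an upper limit of 2.95 on the odds ratio a modest excess from flanking sequence cannot be told apart from none.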
